A study of Homo sapiens with 10 samples.

How the data were processed

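Gene expression was measured by 1-colour Agilent arrays (design 039494) of Cy3-labelled cRNA from 10 samples of 2 human cell lines, SAS and SAS-R, with 1 array for each of 5 conditions per line. Per the file headers, the spot intensities were made with Agilent Feature Extraction 10.7.1.1, although the submitters' processing notes name 9.5.1.1. The processed signal in these files is a background-subtracted (method 7) and spatially detrended intensity on a linear scale, not normalized between arrays. A spot was called well above background by that software at 13 SDs of its background. The deposited value table of the series also holds linear intensities, and these had been quantile normalized by the authors: the sorted columns of the arrays were equal within 0.049% and each had a median of 32.9. How that table was background-corrected and collapsed over spots is not stated. Each column correlated with the same array's processed signal at r = 0.994 or more on the log2 scale across probes. Probe coordinates are those of the deposited files (hg19).

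Quality was read from the files. The arrays had 58717 spots for 50599 non-control probes, 902 of them on 10 spots each, and 0 saturated spots. The 75th percentile of signal ranged from 658.2 to 836.7. For arrays there is no count behind a value, so their number limits the precision. Slide numbers showed 8 arrays on slide 1 and 2 on slide 2, which held SAS-R at 6 and 12 h only.

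Each array's 75th percentile was subtracted from its log2 signals, spots that the software marked as outliers were dropped, and spots of the same probe were averaged. A further 16 probes were left out because every spot was marked on at least 1 array. Probes well above background on at least 4 of the 10 arrays were kept (29497). Of all probes, 28174 (55.7%) took a current gene symbol through a RefSeq accession from a table for the assembly GRCh38.p14, used for names only, and 22425 kept the name in the file. The probe with the highest mean signal stood for its gene, which left 22084 genes. Where a named gene's probes differed by a large part of its own change, their range or the other probe's value is given. Where a gene was not well above background on every array of the dimmer side, its fold is a lower bound, written as at least the stated value. For such a bound every array was raised to a common floor of 5.56% of its 75th percentile, the highest among the arrays of the weakest signal called well above background.

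Groups were taken from the labels. A linear model with a term for each of the 5 time points and a term for the line was fitted in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), with 4 residual degrees of freedom and a variance prior that follows signal (eBayes with trend). It gave the line difference (SAS-R minus SAS at matched times), the irradiation response (mean of 4 irradiated times minus non-irradiated) and the slope per doubling of time from 1 to 12 h. A further term for line by irradiation gave the interaction, SAS-R response minus SAS response, with 3 residual degrees of freedom. Values are log2 changes ± SE, and p-values are two-sided and adjusted over all genes by Benjamini and Hochberg, with a threshold of 0.05. No array had a replicate, so the error comes from departures from the additive model.

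The comparisons, the 29 gene lists, the named-gene rule and all alternatives but 1 were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, lists of at least 3 measured genes, adjusted over lists), then with an estimated correlation and with fry. Their genes were counted over all genes tested and adjusted over the list alone. Between single arrays, a list's median was placed among 10000 random lists matched in 20 bins of signal. The text names FOXM1 throughout. For each comparison it takes from the genes past the threshold the 10 largest changes each way (5 for the interaction) of 2-fold or more that went the same way in every matched pair. That demand was not made of the interaction. From each list it takes up to 4 members past the threshold, or up to 2 with the largest change if none passed. Unnamed loci were not named, and a few genes that the rule takes are left out of the text.

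The fit was tested on simulated data for 22084 genes, of which 200 were changed, 50 at each of 1.5-, 2-, 4- and 8-fold, with independent noise in each gene. It recovered 24%, 64%, 96% and 100% of them for the line difference (7 false calls). For the irradiation response it recovered 8%, 42%, 84% and 96% (13 false calls). For the interaction the shares were 0%, 0%, 32% and 66% (1 false call), and for the slope, with the fold taken from 1 to 12 h, 2%, 28%, 78% and 88% (8 false calls). For the line difference, camera called the shifted list in 20 of 20 simulations and 4 of 560 other lists. The shifted list was that of G1/S and replication, whose correlation in the real data was estimated at 0.666. Genes in the simulations were independent, so these counts do not give the error of camera in these data. The adjusted threshold also depends on how many genes change. In the real line difference 10463 of 22084 genes were called, so the shares recovered above need not hold there.

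The alternatives were background correction by normexp (offset 50), quantile normalization, the authors' table, no filter on weak probes, a filter for signal above background on all arrays, outlier spots kept, the mean of a gene's probes, no trend or a robust prior in eBayes, slide as a term, slide 1 alone, a simpler model without separate time points (for the slope, the irradiated arrays alone), and each array left out in turn. The common floor, also fitted as an alternative for all genes, was chosen after seeing the SAS 12 h array's higher background. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Sex-linked transcripts of the Y chromosome and XIST were not reported.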

Results

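Gene expression was measured in SAS, an established line of human oral squamous cell carcinoma cells, and in SAS-R, which the series sets beside it in a study of radioresistance. The labels do not say how SAS-R was obtained. Each line was given X-rays in daily fractions of 2 Gy for 5 days, 10 Gy in all. Total RNA was taken at 4 times after the last fraction (1, 3, 6 and 12 h), and from non-irradiated cells of the same line. The 10 groups held 1 array each, 5 per line, so no group had replicates. A p-value here measures the spread between these 10 arrays around a fitted model, and no label says that they came from separate cultures. Nor does any say when the non-irradiated cells were taken, so time in culture over the 5 days may differ along with irradiation in each value set against them.

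The arrays held 50599 probes, of which 26586 to 30290 were well above background on 9 arrays and 23310 on the SAS 12 h array. The weakest signal called well above background was 40.8 on that array and 11.04 to 21.62 on the others, so weak transcripts were measured least well there. No spot was saturated. Across genes, log2 signals of arrays of the same line correlated at r = 0.968 to 0.992, and those of different lines at 0.914 to 0.932. The first principal component held 69.6% of the variance and separated the lines. The second held 9.9%, and on it the non-irradiated array of each line lay at the opposite end from its 1 h or 3 h array. All 5 SAS arrays and the SAS-R non-irradiated, 1 h and 3 h arrays shared a slide. The SAS-R 6 h and 12 h arrays were on another, so slide 2 held a single line. For the line difference and the interaction, a slide term and slide 1 alone therefore both rest on the non-irradiated, 1 h and 3 h pairs. They give the same estimates and are not separate checks, nor can they tell slide from time.

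The first question was how SAS-R differed from SAS at matched times, with FOXM1, the transcription factor in the series title, asked about first. FOXM1, which drives transcription of mitotic genes, was 1.63-fold higher in SAS-R, a log2 difference of 0.71 ± 0.14 (SE, adjusted p = 0.00408). It was higher in 5 of 5 matched pairs, by 0.31 without irradiation and by 1.01, 0.48, 1.12 and 0.62 at 1, 3, 6 and 12 h. Its probe lies on chromosome 12 at 2967322 to 2967381 (hg19). On the 8 arrays of slide 1 alone the FOXM1 difference was 0.60 ± 0.19 and no longer passed (adjusted p = 0.0628), and with slide as a term in the fit it was 0.60 ± 0.18 (adjusted p = 0.0386).

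**Figure D1:**
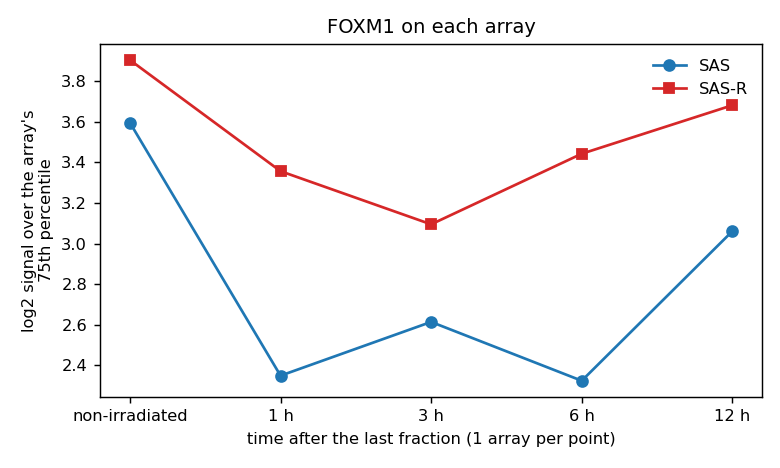
FOXM1 signal on each of the 10 arrays, as log2 signal over the array's 75th percentile, against time after irradiation for SAS and SAS-R, with the non-irradiated array of each line at the left. SAS went from 3.596 without irradiation to 2.35 at 1 h and 3.06 at 12 h, and SAS-R from 3.91 to 3.36 and 3.68.

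The largest differences between the lines were far larger than that of FOXM1. Many of these transcripts were not well above background on every array of the dimmer line, so their folds are lower bounds with all arrays raised to a common floor. ADAMTS1, a secreted metalloprotease, was at least 469-fold higher in SAS-R, XAGE1A, a cancer-testis antigen, at least 240-fold and SCG5 at least 189-fold. NFAM1 was at least 172-fold higher, GARIN1B at least 133-fold, SH3BGRL at least 74.0-fold and ADAM18 at least 72.8-fold. CCL5, a chemokine, was at least 58.0-fold higher and CYP2J2, an arachidonic acid epoxygenase, at least 37.2-fold. XAGE1A, ADAM18, CCL5 and CYP2J2 were well above background on 0 of the 5 SAS arrays, ADAMTS1, NFAM1 and SH3BGRL on 1, GARIN1B on 3 and SCG5 on 4. DEFB103B, which encodes an antimicrobial beta-defensin and was measured on all arrays, was 414-fold higher. In the other direction, SAS-R had less EEF1A2, a translation elongation factor (log2 difference -10.09 ± 0.15), and less H19, an imprinted noncoding RNA (-8.59). BCAT1, which starts the breakdown of branched-chain amino acids, was at least 141-fold lower by its brightest probe, and its probes differed, from -10.39 to -4.60. BTG3 was at least 117-fold lower, DPYSL5 at least 88.9-fold, KCNJ18 at least 78.2-fold and MRFAP1L1 at least 46.8-fold, each with 0 of the 5 SAS-R arrays well above background. GAL (at least 217-fold lower) and CLIC3 (at least 152-fold) were well above background on 1 of the 5 SAS-R arrays, and another GAL probe gave -0.39.

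Cholesterol genes were mostly lower in SAS-R. Of 20 measured genes of cholesterol synthesis and uptake, 17 were lower in SAS-R and 1 higher, with the same counts when adjusted over the list alone and a median log2 difference of -1.72. They included MVD (-2.58 ± 0.16), INSIG1 (-2.51), CYP51A1 (-2.48) and SQLE (-2.33), which make or regulate sterols. The camera test gave adjusted p = 2.18e-07, and adjusted p = 0.436 with an estimated correlation. Interferon-stimulated genes were mostly higher, 18 of 29 against 6 lower (19 and 6 adjusted over the list alone), with a median of 1.33 (adjusted p = 0.0201, and adjusted p = 0.806 with an estimated correlation). RSAD2, an antiviral enzyme, was at least 5.42-fold higher, IFI44 26.7-fold and OASL 23.7-fold. IRF7, a transcription factor of the interferon response, went the other way, at least 89.4-fold lower, and was well above background on 1 of the 5 SAS-R arrays.

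FOXM1's late cell cycle targets, the genes of G2 and mitosis, were higher in SAS-R in 16 of 30 cases and lower in 1 (17 and 1 adjusted over the list alone). KIF20A (1.43 ± 0.29) and KIF23 (1.14), mitotic kinesins, CCNB1 (1.35 ± 0.18), the mitotic cyclin B1, and CENPA (1.11), a centromeric histone, rose most from SAS to SAS-R. The list median was 0.58 (adjusted p = 0.0201, and adjusted p = 0.806 with an estimated correlation). Between the non-irradiated arrays the median of this list was -0.10, against 1.07, 0.85, 0.92 and 0.09 at 1, 3, 6 and 12 h. Of 27 genes of G1/S and replication, 11 were higher and 2 lower, both over all genes and adjusted over the list alone, and that list did not pass (adjusted p = 0.0751). GINS2 (1.77) and CDC45 (1.04) act at the replication fork, E2F2 (1.15) is an E2F activator, and RRM2 (1.05) is a subunit of ribonucleotide reductase whose probes ranged from -1.31 to 2.20.

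Because the series concerns reactive oxygen species, redox genes were counted as 3 groups. NRF2 targets were lower in 10 of 23 cases and higher in 2, unchanged when adjusted over the list alone, with a median of -0.28 (adjusted p = 0.0201, and adjusted p = 0.436 with an estimated correlation). NQO1, a quinone reductase, was 6.16-fold lower (-2.62), TXNRD1, which reduces thioredoxin, was lower by a log2 difference of -1.94, and SLC7A11, the cystine importer, by -1.65. CBR1, a carbonyl reductase, was at least 22.1-fold lower. Antioxidant enzymes went both ways, 8 of 22 higher and 8 lower (9 and 8 adjusted over the list alone). GLRX (1.40) and PRDX4 (1.1, with another probe at 1.91) were higher and PRDX5 (-1.25) and PXDN (-2.21) lower, and the list did not pass (adjusted p = 0.993). Of 10 oxidases that produce reactive oxygen species, 3 were higher and 5 lower, as when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.94) but passed fry as higher (adjusted p = 0.0139). MAOA, a monoamine oxidase, was 7.91-fold higher, while DUOXA1 was lower (-0.97).

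Epithelial junction genes were lower in SAS-R in 10 of 21 cases and higher in 1, the same adjusted over the list alone (median -0.47, adjusted p = 0.0201, and adjusted p = 0.436 with an estimated correlation). They included the claudins CLDN4 (-1.95), CLDN7 (-1.56) and CLDN3 (at least 12.2-fold lower, well above background on 1 of the 5 SAS-R arrays) and the scaffold TJP1 (-1.57). Basal keratinocyte genes were higher in 10 of 19 cases and lower in 3 (10 and 4 adjusted over the list alone), among them the keratins KRT14 (3.23, with probes up to 8.82) and KRT17 (2.91), COL17A1 (2.73) and the integrin ITGA6 (1.55), and the list did not pass camera (adjusted p = 0.0832) but passed fry as higher (adjusted p = 0.00238). Of 24 differentiation and cornification genes, 11 were higher and 5 lower (11 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.234) but passed fry as higher (adjusted p = 0.0164). CRCT1 was 50.1-fold higher, KRT6A 36.8-fold, and KLK5 was at least 164-fold lower, well above background on 3 of the 5 SAS-R arrays. FLG was well above background in SAS-R alone, its probes ranged from 0.68 to 3.89, and its difference did not pass with all arrays at the common floor (adjusted p = 0.138). Of 18 mesenchymal genes, 7 were higher and 6 lower (8 and 6 adjusted over the list alone, median 0.26, mean -0.30). That list did not pass camera (adjusted p = 0.94) but passed fry as lower (adjusted p = 0.000813). ZEB1, a repressor of epithelial genes, was at least 4.49-fold higher, while VIM (-2.73) and AXL (-2.37) were lower and TWIST2 was at least 30.4-fold lower. Matrix proteases and their inhibitors were higher in 13 of 22 cases and lower in 5, also adjusted over the list alone (adjusted p = 0.0609 by camera, not passing, and 0.00899 by fry, as higher). MMP3 was 10.1-fold higher, and PLAU, the urokinase, was lower (-7.99).

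Among the remaining lists, immediate early genes were higher in 12 of 22 cases and lower in 3 (13 and 3 adjusted over the list alone, median 0.78, adjusted p = 0.0201, and adjusted p = 0.436 with an estimated correlation). FOSB (3.18) and GADD45B (2.35) were higher, EGR3 was at least 5.65-fold higher and CCN2 at least 3.53-fold lower. Of 9 measured cancer-testis antigens on the list, XAGE1A not among them, 5 were lower and 1 higher, as when adjusted over the list alone. The higher member, PAGE2, was well above background on 0 of the 5 SAS arrays and did not pass with the common floor (adjusted p = 0.402). MAGEA4 was at least 17.3-fold lower and MAGEA1 at least 15.4-fold (list median -0.80, adjusted p = 0.0304, and adjusted p = 0.436 with an estimated correlation). Genes of MHC class I and antigen processing were higher in 6 of 17 cases and lower in 1 (5 and 0 adjusted over the list alone), such as B2M (1.28), with a median of 0.38 (adjusted p = 0.0436, and adjusted p = 0.806 with an estimated correlation). Ribosomal protein genes, kept as a comparison list, were lower in 19 of 25 cases and higher in 0, unchanged when adjusted over the list alone (median -0.34, adjusted p = 2.43e-05, and adjusted p = 0.806 with an estimated correlation). RPL30 and RPL7 were among those lower, RPL30 by a log2 difference of -1.1. Repair genes did not pass as lists by camera or fry: 9 of 19 genes of homologous recombination were higher and 2 lower (adjusted p = 0.0832), and 10 of 25 of end joining and damage signalling were higher and 8 lower (adjusted p = 0.893). Among repair genes, RAD51AP1 (1.56), FANCB (1.55) and DCLRE1C (1.52) were higher and PRKDC (-1.35) and POLM (-2.03) lower. For p53 targets, 6 of 28 were higher and 7 lower, with MDM2, the p53 ubiquitin ligase, at -1.44 (probes from -1.59 to -0.30) and TP53INP1 at least 4.46-fold lower (adjusted p = 0.94). Among markers of other cell types, 1 of 3 fibroblast genes was lower, 4 of 9 leukocyte genes were higher and 1 lower, and 2 of 5 endothelial genes were higher and 1 lower. By camera none of these 3 lists passed, and by fry, which does not compare a list with other genes, all 3 did (adjusted p = 0.0229, 0.00238 and 0.0119).

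**Figure D2:**
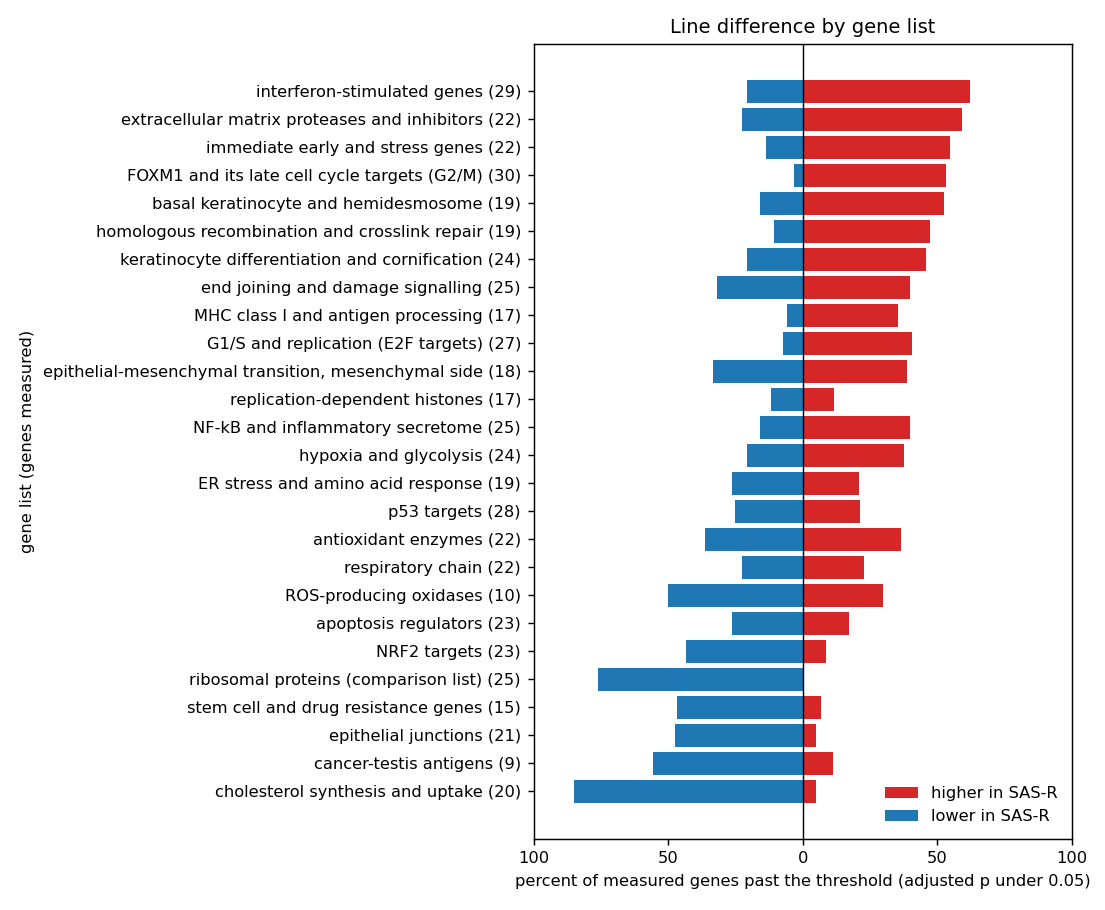
Percent of each gene list's measured genes that passed the test between the lines (adjusted p under 0.05), drawn to the right if higher and to the left if lower in SAS-R, with the number measured in brackets and lists ordered by their median difference. The cholesterol list, at the bottom, had 17 of 20 genes lower, and the interferon list, at the top, 18 of 29 higher.

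Over all genes, limma called 10463 of 22084 different between the lines, 5329 higher and 5134 lower in SAS-R, and 4545 of them by 2-fold or more. The same direction held in all 5 matched pairs for 9629. Pairs that disagree add to the error and make a call less likely, so this is no further support. On slide 1 alone 6604 genes passed, of which 6405 were also called on all arrays, and with slide as a term 8237 passed. Of the 9 lists that passed camera, 0 passed with an estimated correlation, and fry called 18. With slide as a term and on slide 1 alone the medians were -1.57 for the cholesterol list, 1.72 for the interferon list and 0.62 for the G2 and mitosis list.

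The second question was what the fractionated irradiation changed in both lines, as the mean of the irradiated times minus the non-irradiated array. SPRR2A, a cornified envelope protein, was 14.8-fold higher (log2 change 3.89 ± 0.59, adjusted p = 0.0376) and FOSB, an AP-1 subunit, 8.06-fold (3.01 ± 0.38, adjusted p = 0.0274). IFITM1, an interferon-induced membrane protein, was 7.7-fold higher (2.94 ± 0.30, adjusted p = 0.0163) and IGFL1 6.28-fold. RRAD, CSGALNACT1, SERPINB4, PYY and COX8C also passed as higher and DNAJB13 as lower. Each of these 6 was not well above background on at least 1 array. With all arrays at the common floor the log2 change was 2.46 for RRAD, 1.07 for CSGALNACT1, 1.08 for SERPINB4, 0.10 for COX8C, 0 for PYY and -1.21 for DNAJB13. Lower after irradiation were the histone genes H1-1 (-2.31 ± 0.32) and H3C4 (-1.57), MMP3, a stromelysin (-2.28), E2F1, the S-phase transcription factor (-1.28 ± 0.19, adjusted p = 0.0365), and POLA1, a subunit of the replicative polymerase that primes DNA (-1.25 ± 0.14, adjusted p = 0.02). ABCD3 (-1.43), ACTL8 (-1.40), DLEU2L (-1.38) and GLIDR (-1.18) were lower as well. All of these genes went the same way on 8 of 8 irradiated arrays, as the naming rule demands, so this is no further support. The 8 changes also share 1 non-irradiated array per line.

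FOXM1 was lower on 8 of 8 irradiated arrays, by a mean log2 change of -1.01 in SAS and -0.51 in SAS-R, but its mean change of -0.76 ± 0.17 did not pass (adjusted p = 0.0777). Without the SAS-R 1 h array it passed (-0.81 ± 0.17, adjusted p = 0.043).

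Proliferation genes were shifted down by the camera test. Of 17 replication-dependent histone genes, 1 was lower over all genes tested and 16 were adjusted over the list alone, with a median of -1.27 (adjusted p = 1.43e-12, and adjusted p = 0.273 with an estimated correlation). Of 27 genes of G1/S and replication, 2 were lower over all genes and 18 adjusted over the list alone, with a median of -0.77 (adjusted p = 2.62e-12, and adjusted p = 0.327 with an estimated correlation). Their median in SAS was -1.76 at 1 h and 0.12 at 12 h, and in SAS-R -0.91 and -0.12. For the G2 and mitosis list, 0 of 30 genes passed either way, and the median was -0.52 (adjusted p = 3.38e-07, and adjusted p = 0.396 with an estimated correlation). Homologous recombination genes had a median of -0.50, with 0 of 19 lower over all genes and 1 adjusted over the list alone (adjusted p = 2.93e-05, and adjusted p = 0.344 with an estimated correlation).

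Inflammatory genes went up together by the camera test. Of 25 NF-kB and secretome genes, 5 were higher over all genes and 13 adjusted over the list alone (median 0.84, adjusted p = 2.43e-10, and adjusted p = 0.221 with an estimated correlation). They included the cytokine CSF2 (2.26), the survival factor BIRC3 (2.02), TNFAIP3, an inhibitor of NF-kB (1.89 ± 0.18, adjusted p = 0.0163). CXCL3 was also called, but was not well above background on either non-irradiated array, and its change was 0.13 with the common floor (adjusted p = 0.766). Of 22 immediate early genes, 3 were higher and 11 adjusted over the list alone (median 0.68, adjusted p = 2.16e-10, and adjusted p = 0.0938 with an estimated correlation), with FOS at 2.61 on 7 of 8 arrays and EGR3 at 1.91, or 1.30 and not passing with the common floor (adjusted p = 0.134). Of 29 interferon-stimulated genes, 1 was higher, IFITM1, and 11 adjusted over the list alone (median 0.64, adjusted p = 1.39e-08, and adjusted p = 0.327 with an estimated correlation). Cornification genes had 2 of 24 higher, SPRR2A and CRCT1 (1.90), and adjusted over the list alone 7 higher and 1 lower (adjusted p = 2.93e-05, and adjusted p = 0.221 with an estimated correlation). Among basal keratins, KRT14 (1.19) and KRT17 (1.05) rose and KRT5 (-0.75) fell. Of 28 p53 targets only CDKN1A, the cyclin-dependent kinase inhibitor p21, was higher, 2.29-fold (1.19 ± 0.18, adjusted p = 0.0379), and the list did not pass (adjusted p = 0.195). NDRG1 (1.77), MAOA (0.71) and FN1 (0.84) also rose. Of 23 NRF2 targets 0 passed, and neither the NRF2 list (adjusted p = 0.949) nor the cholesterol list (adjusted p = 0.955) was shifted. Leukocyte markers, a check for other cell types, had a median of 0.53 (adjusted p = 0.011, and adjusted p = 0.221 with an estimated correlation), with 0 of 9 higher over all genes and 1 adjusted over the list alone.

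**Figure D3:**
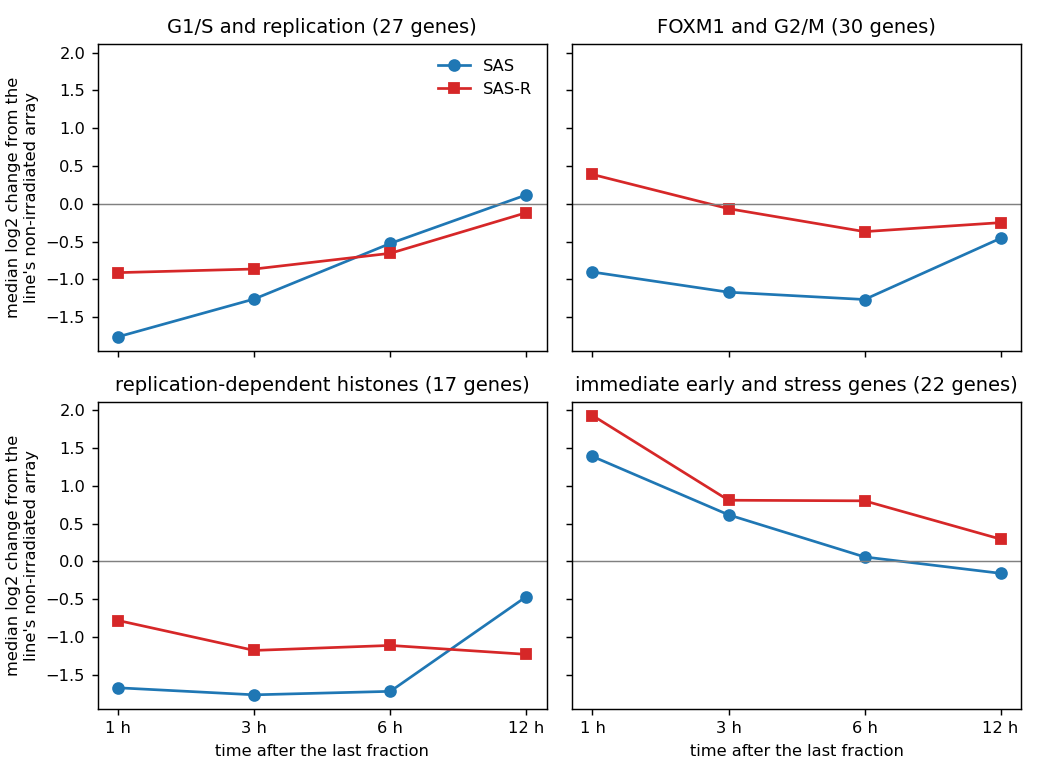
Median log2 change of 4 gene lists against the same line's non-irradiated array at 1, 3, 6 and 12 h (drawn at equal spacing), for SAS and SAS-R, 1 array per point. The G1/S and replication list went from -1.76 at 1 h to 0.12 at 12 h in SAS, and the G2 and mitosis list lay at -1.27 in SAS and -0.37 in SAS-R at 6 h.

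In all, limma called 190 of 22084 genes after irradiation, 146 higher and 44 lower, 150 of them by 2-fold or more, and 184 went the same way on 8 of 8 arrays. Disagreement between the lines adds to the error, so that agreement is partly built into the call. With slide as a term 42 genes passed, on slide 1 alone 0 passed (2801 at an unadjusted p under 0.05), and with weak signals raised to the common floor 23 passed, 13 higher and 10 lower. Of the 34 genes called here that the naming rule takes, 3 passed with the common floor, and those lost included genes well above background on all 10 arrays, such as SPRR2A (adjusted p = 0.134), FOSB (0.126), IFITM1 (0.091) and E2F1 (0.105), whose log2 changes there were 3.89, 2.63, 2.94 and -1.28. The count was 0 without the SAS 3 h, SAS 6 h, SAS-R 3 h or SAS-R 6 h array (3379 to 3560 at an unadjusted p under 0.05), 49 without the SAS non-irradiated array, 83 without SAS 12 h, 102 without SAS-R 12 h and 1171 without SAS-R 1 h, where 585 were higher and 586 lower. Of the 21 lists that passed camera, 0 passed with an estimated correlation. With slide as a term the medians were -0.54 for the G1/S list, -1.1 for histones, 0.94 for NF-kB genes and 0.91 for interferon-stimulated genes, and on slide 1 alone they were equal to these.

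The third question was whether the lines responded differently, tested as the interaction of line and irradiation. TREM1, a receptor that amplifies inflammatory signals, was higher after irradiation in SAS and lower in SAS-R (fitted interaction -6.95 ± 0.38, adjusted p = 0.0116). It was well above background on all 5 SAS arrays and, in SAS-R, only on the non-irradiated array, so the fitted size rests on background. With all arrays at the common floor the changes were 2.83 in SAS and -1.79 in SAS-R and the interaction -4.62 ± 0.34 (adjusted p = 0.0263), and a second TREM1 probe gave -1.73. LCN2, a secreted iron-siderophore binding protein, reached 73.4% to 112.2% of the array's 75th percentile on the irradiated SAS arrays. It was not well above background on the non-irradiated SAS array or on any SAS-R array, so its fitted interaction of -6.40 ± 0.44 (adjusted p = 0.0269) rests on background. At the common floor it was -4.09 ± 0.28 (adjusted p = 0.0225). ARL3, a small GTPase of cilia, was lower after irradiation in SAS-R, at 9.48% to 12.5% of the 75th percentile against 110.7% without irradiation, and its mean change in SAS was 0.70 (interaction -4.03 ± 0.34, adjusted p = 0.0484). GPNMB, a transmembrane glycoprotein, had a mean change of 2.27 in SAS and -0.98 in SAS-R (interaction -3.25 ± 0.24, adjusted p = 0.0286), and its other probe gave -1.39.

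**Figure D4:**
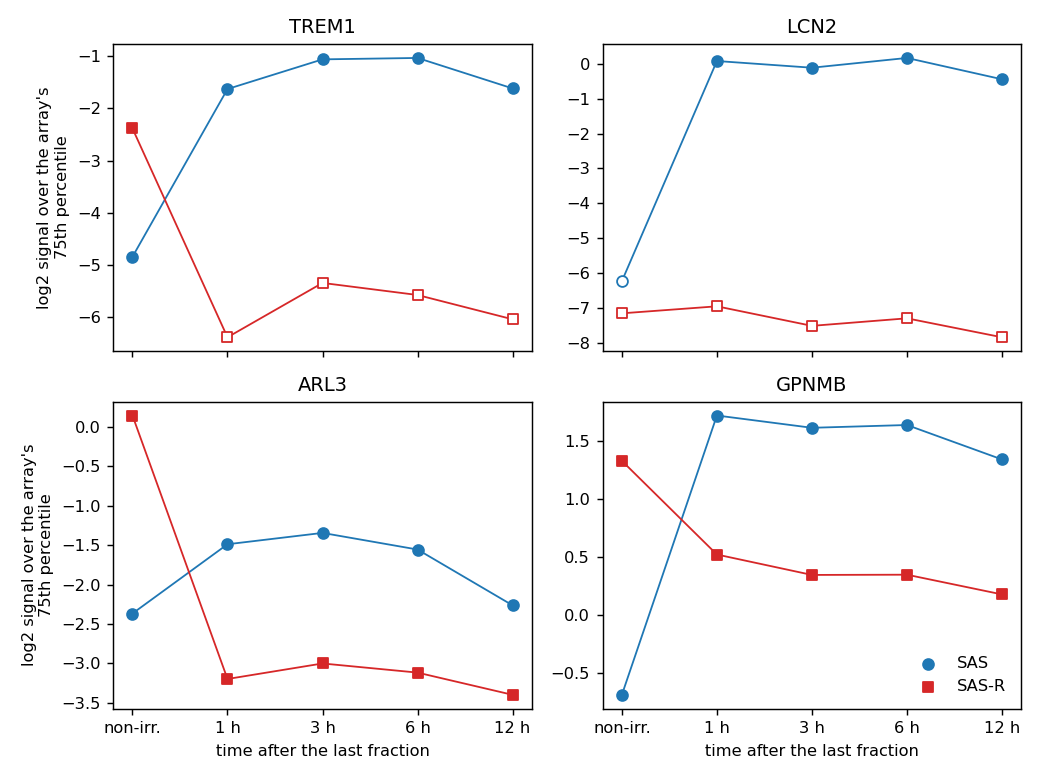
Signal of TREM1, LCN2, ARL3 and GPNMB on the 10 arrays as log2 signal over the array's 75th percentile, by hours after irradiation, for SAS and SAS-R. Open markers are signals not well above background, which for LCN2 include all 5 SAS-R arrays.

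The irradiation response of the G2 and mitosis list differed between the lines by camera. Its median change was -0.96 in SAS and -0.10 in SAS-R, and 29 of 30 members had a positive interaction (median 0.81, adjusted p = 1.84e-08, and adjusted p = 0.713 with an estimated correlation). No single member passed, also adjusted over the list alone. In SAS the list median was -0.90, -1.17, -1.27 and -0.46 at 1, 3, 6 and 12 h. In SAS-R it was 0.39, -0.07, -0.37 and -0.25. For FOXM1 the interaction was 0.50 ± 0.31 and did not pass (adjusted p = 0.689). Matrix proteases (median 0.90, adjusted p = 5.33e-05, and adjusted p = 0.611 with an estimated correlation) and hypoxia and glycolysis genes (median 0.50, adjusted p = 2.06e-05, and adjusted p = 0.611 with an estimated correlation) were shifted toward SAS-R as well. Cholesterol genes were shifted the other way (median -0.42, adjusted p = 0.00185, and adjusted p = 0.713 with an estimated correlation), with a median response of 0.23 in SAS and -0.22 in SAS-R.

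For the interaction limma called 4 of 22084 genes (2059 at an unadjusted p under 0.05), all lower, and 8 lists by camera, of which 0 passed with an estimated correlation or with fry. It rests on 1 non-irradiated pair and could not be fitted without either of those arrays. The count was 0 without the SAS 3 h, SAS 6 h, SAS-R 3 h or SAS-R 6 h array (1287 to 1407 at an unadjusted p under 0.05) and 8 without either 12 h array. With slide as a term 7 genes passed and on slide 1 alone 743, the 4 genes among them in each case, with weak signals raised to the common floor 215, and among probes above background on all arrays 0 (1596 at an unadjusted p under 0.05). The G2 and mitosis median was 1.14 with slide as a term and on slide 1 alone. Both rest on the non-irradiated, 1 h and 3 h pairs alone, so time points changed along with the slide.

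The last question was how expression moved between 1 and 12 h, fitted as a slope per doubling of time over both lines. Immediate early genes fell with time. FOS, an AP-1 subunit, had a slope of -1.62 ± 0.11 (adjusted p = 0.0152), 56.4-fold from 1 to 12 h, and FOSB -1.40 ± 0.13, or 32-fold. CCN2 (-1.19), ATF3 (-1.05, with another probe at -0.07), EGR2 (-0.93) and EGR1 (-0.83) fell too. CCN2 and EGR2 were not well above background on every array, and with the common floor their slopes were -1.03 and -0.67. GDF15, a stress-induced cytokine and p53 target, had a slope of -0.84, or 8.01-fold. Of 22 immediate early genes, 10 fell over all genes and 15 adjusted over the list alone (median slope -0.39, adjusted p = 1.1e-15). This was the only call of a list in any comparison that passed with an estimated correlation (adjusted p = 0.0411 with an estimated correlation).

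Replication genes rose over the same hours. E2F1 had a slope of 0.59 ± 0.06, 4.36-fold from 1 to 12 h, GINS2 one of 0.57, E2F2 0.52 and CDC6, a licensing factor, 0.48. Of 27 genes of G1/S and replication, 10 rose over all genes and 27 adjusted over the list alone (median slope 0.39, adjusted p = 2.6e-19, and adjusted p = 0.677 with an estimated correlation). Homologous recombination genes had a median slope of 0.19, with 1 of 19 higher both over all genes and adjusted over the list alone (adjusted p = 2.94e-05, and adjusted p = 0.677 with an estimated correlation). By line that median was 0.373 in SAS and 0.033 in SAS-R, so the rise lay mostly in SAS. For the G1/S list the medians were 0.523 and 0.191. These differences between the lines were not tested. MRTO4 (0.64) and UTP20 (0.60), which act in ribosome assembly, and PIGW (0.54) rose as well. EGLN3, an oxygen-sensing prolyl hydroxylase, had a slope of 0.65 ± 0.09, but was well above background on 7 of 10 arrays, and with the common floor its slope was 0.12 (adjusted p = 0.428). Genes of endoplasmic reticulum stress had a median slope of -0.16, with 2 of 19 lower, among them TRIB3 (-0.43), and adjusted over the list alone 9 lower and 1 higher (adjusted p = 0.000135, and adjusted p = 0.677 with an estimated correlation). The p53 targets CDKN1A (-0.39) and BBC3 (-0.57) fell, as did SLC7A11 (-0.59), the oxidase activator NOXA1 (-0.48) and KLF4 (-0.53). The p53 list did not pass (adjusted p = 0.237). The FOXM1 slope was 0.13 ± 0.06 and did not pass (adjusted p = 0.284).

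The slope passed in limma for 545 of 22084 genes, 313 rising and 232 falling, with the same sign in each line for all 545. Slopes that differ between the lines add to the error of this fit, so the shared sign is no further support. It passed for 3 genes with slide as a term, for 0 on slide 1 alone (2600 at an unadjusted p under 0.05), for 96 without an intensity trend in the variance and for 220 with weak signals raised to the common floor. Of the 35 genes called for the slope that the naming rule takes, 8 passed with the common floor, FOS, FOSB, E2F1, MRTO4, UTP20, PIGW and SLC7A11 among them, and CCN2 (adjusted p = 0.0725), EGR2 (0.232), ATF3 (0.0918), EGR1 (0.0547), GDF15 (0.0669), CDKN1A (0.0669), GINS2 (0.114) and E2F2 (0.112) did not. The slopes there were -1.05 for ATF3, -0.83 for EGR1, -0.84 for GDF15, -0.39 for CDKN1A, 0.57 for GINS2 and 0.52 for E2F2, as without the floor. It passed for 0 genes without any 1 of the SAS or SAS-R arrays at 3, 6 or 12 h (3334 to 3946 at an unadjusted p under 0.05) and for 266 without the SAS 1 h array. The median slope of the immediate early list was -0.37 with slide as a term and -0.39 on slide 1 alone, and that of the G1/S list 0.47 and 0.46. Of 35 genes called for both irradiation and slope, 34 had opposite signs.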

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

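The tests of the non-irradiated arrays and of the scaling were chosen after the result they bear on had been seen, and the test of the slide before.

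The irradiation response of 4 genes differed between the lines by the interaction test. TREM1 (-6.954) went up in SAS and down in SAS-R, where it was not well above background on any irradiated array. LCN2 (-6.398) was well above background only on the irradiated SAS arrays. Both sizes rest on background, and with all arrays at the common floor they were -4.62 and -4.09. ARL3 (-4.03) was highest on the SAS-R non-irradiated array, and GPNMB (-3.249) went up in SAS and down in SAS-R. Each of the 4 values takes its starting point from 1 non-irradiated array per line. TREM1 passed in 15 of 20 alternatives, LCN2 in 16 of 20, GPNMB in 14 of 21 and ARL3 in 10 of 21. These alternatives are not all separate, as either array of a matched pair left out gives nearly the same fit.

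The irradiation response of 8 gene lists also differed between the lines by camera, none of them with an estimated correlation or with fry. The medians of the interaction were 0.904 for extracellular matrix proteases and inhibitors, 0.497 for hypoxia and glycolysis, 0.393 for basal keratinocyte genes, 0.379 for the respiratory chain and 0.344 for endoplasmic reticulum stress. They were -0.418 for cholesterol synthesis and -0.136 for ribosomal proteins. The call was kept in 11 of 23 alternatives for endoplasmic reticulum stress and in 13 for ribosomal proteins. For the others of the 8 lists it was kept in 20 or 21.

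The remaining list, FOXM1 and its late cell cycle targets, had a median interaction of 0.806 (95% bootstrap interval over genes 0.653 to 1.042), with a median change after irradiation of -0.957 in SAS and -0.095 in SAS-R. Against a start that already differed, the non-irradiated lines were within a median of -0.096 of each other (-0.185 to 0.045). On slide 1 alone the median was 1.136, so the difference was present without the arrays of slide 2. That fit rests on the non-irradiated, 1 h and 3 h pairs, so it cannot tell slide from time at 6 and 12 h. Against the scaling, the lowest of 3 scalings gave 0.729. A biological difference between the lines in their response stays open and untested. A different state of a single culture or array among the non-irradiated ones stays open, as genes are not independent replicates and each line had 1 such array.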

How the results depend on the processing

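The common floor was chosen after seeing the data, and the other alternatives before. Of the 4 counts of genes under these alternatives, 49 values stayed within 1.5 times that reported and 41 did not. FOXM1 stayed higher in SAS-R past the threshold in 22 of 23 alternatives (adjusted p 0.00186 to 0.0628), and its irradiation response passed in 1 of 23 (adjusted p 0.043 to 0.453). The alternatives are not all separate checks. For the line difference and the interaction, leaving out either array of a matched pair gives nearly the same fit (8239 and 8241 genes for the line difference at 3 h). Quantile normalization and the authors' table are also nearly the same (10521 and 10527). Over genes named and alternatives, 3918 results were the same, 846 weaker, 11 stronger and 1 reversed. Over lists the numbers were 885 the same, 147 weaker and 2 reversed.

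The line difference (10463) was 6604 on slide 1 alone, which holds fewer arrays, and 8239 to 10123 with an array left out. The irradiation count (190) was 106 with normexp, 81 without the intensity trend, 42 with slide as a term, 0 on slide 1 alone and 23 with the common floor. It was 0 to 1171 with an array left out. The interaction (4) was 7 with normexp, 19 without the filter, 0 among probes above background on all arrays, 1 with the mean of a gene's probes and 2 without the intensity trend. It was 7 with slide as a term, 743 on slide 1 alone, 16 in the simpler model, 215 with the common floor and 0 to 8 with an array left out. It could not be fitted without either non-irradiated array. The slope count (545) was 96 without the intensity trend, 3 with slide as a term, 0 on slide 1 alone, 1425 in the simpler model and 220 with the common floor. It was 0 to 740 with an array left out. The floor leaves genes raised to it on all arrays with no spread. Apart from the fewer arrays in those fits, the cause was not tested.

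HLA-B reversed between the lines with the mean of its probes, from 0.98 to -1.4, with adjusted p from 7.05e-05 to 0.00679 over its alternatives. Its 3 probes ranged from -5.73 to 0.98. After irradiation, the camera direction of the respiratory chain list reversed without the SAS non-irradiated array, at a median of -0.042 (adjusted p = 0.748), and its medians with an array left out were -0.458 to -0.042. That of the matrix protease list reversed without the SAS-R non-irradiated array, at 0.023 (adjusted p = 0.545), with medians of 0.023 to 0.541. The cause was not tested. Background limits weak transcripts: the weakest signal called well above it was 40.8 on the SAS 12 h array and at most 21.6 on the others.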

Other observations

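The tests in this part, on chromosome neighbours and on other splits of the arrays, were set before their results were seen.

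Further lists passed camera after irradiation, none with an estimated correlation. Among them was the ribosomal comparison list, with a median log2 change of 0.107 (0 of 25 higher, adjusted p = 0.00281, and adjusted p = 0.531 with an estimated correlation). It passed camera between the lines and for the interaction too. Its estimated correlation was 0.781 against the preset 0.01, so a camera pass at the preset value alone is weak evidence. A fail with an estimated correlation does not by itself show correlated genes, as that setting also uses the few residual degrees of freedom. Between the lines, epithelial junction and cancer-testis genes had estimated correlations of -0.011 and 0.024. Their unadjusted camera p still went from 0.00484 and 0.00838 to 0.0367 and 0.0662. Genes of endoplasmic reticulum stress had a median log2 change of 0.40 (adjusted p = 0.00175, and adjusted p = 0.377 with an estimated correlation), 0.04 in SAS and 0.57 in SAS-R. Genes of MHC class I and antigen processing had a median of 0.28 (0 of 17 higher over all genes, 5 adjusted over the list alone, adjusted p = 0.00371, and adjusted p = 0.371 with an estimated correlation). Epithelial junction genes had a median of 0.34 (0 of 21 over all genes, 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0138, and adjusted p = 0.221 with an estimated correlation). Genes of end joining and damage signalling had a median of -0.28 (0 of 25 over all genes, 3 lower adjusted over the list alone, adjusted p = 0.00053, and adjusted p = 0.233 with an estimated correlation). Antioxidant enzymes had a median of -0.23 (0 of 22 over all genes, 1 higher and 6 lower adjusted over the list alone, adjusted p = 0.0417, and adjusted p = 0.47 with an estimated correlation). That call was kept in 12 of 25 alternatives. Oxidases that produce reactive oxygen species had a median of 0.155 (2 of 10 higher, adjusted p = 0.0124, and adjusted p = 0.327 with an estimated correlation).

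Between the lines, stem cell and drug resistance genes were lower in SAS-R in 7 of 15 cases and higher in 1, and the list did not pass camera (adjusted p = 0.0751) but passed fry as lower (adjusted p = 0.000813). Hypoxia and glycolysis genes were higher in 9 of 24 cases and lower in 5 (adjusted p = 0.216), and NF-kB genes in 10 of 25 and 4 (adjusted p = 0.348 by camera, and 0.0358 by fry, as higher). Among NF-kB genes CSF2 was 39.4-fold higher in SAS-R, CCL2 at least 7.63-fold lower and LTB at least 3.1-fold lower. The interferon list's median difference, SAS-R minus SAS, was 1.55 without irradiation and 1.53, 1.36, 1.16 and 0.35 at 1, 3, 6 and 12 h. Against the non-irradiated array, the same list's median in SAS was 0.60 at 1 h and 1.38 at 12 h, and in SAS-R 0.56 and 0.20. Histone genes at 12 h had a median change of -0.47 in SAS and -1.23 in SAS-R. These differences between times and lines were not tested.

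Line differences of neighbouring genes ran together along chromosomes. Each difference was first limited to 2 log2 units either way. The value r is the mean product of deviations over pairs, divided by the variance over genes. Over 283066 pairs 1 to 3 Mb apart, among 16129 autosomal genes well above background on all arrays, r was 0.077. In 1000 permutations of gene positions it was at most 0.00624 (p = 0.001, the smallest they can give). Pairs that far apart argue against probes reading shared transcripts, and 0% of permutations within signal bins were as high. The irradiation response gave r = 0.028, under that of the line difference but above its own permutations (at most 0.00696). Neighbouring genes therefore ran together in both comparisons. The 2 values were computed separately, so they do not tell how much of the line difference's r is particular to the lines. Of 249 windows of 10 Mb, 5 had a median line difference of 0.5 or more either way, against at most 2 in permutations, which may fit a difference in gene dosage between the lines that these arrays do not measure directly.

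All 5 windows were lower in SAS-R. They lie on chromosome 14 at 100000001 to 110000000 (hg19, 79 genes, median -0.72, 58 genes lower), chromosome 8 at 90000001 to 100000000 (42 genes, -0.69, 36 lower), chromosome 3 at 100000001 to 110000000 (28 genes, -0.67, 23 lower), chromosome 12 at 60000001 to 70000000 (35 genes, -0.61, 28 lower) and chromosome 10 at 80000001 to 90000000 (45 genes, -0.55, 33 lower).

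Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, only 1, the real one, called as many genes for the line difference. It called 10463 and the highest of the others 0. Every other split, here and below, mixes the lines, so the large difference between them adds to its error. Few calls could come from such splits. They therefore cannot tell a difference between the lines from one between single cultures. Of the 16 splits that part all 5 matched pairs, 1, the real one, called as many, with 10463 against at most 0, and 16 splits are too few for a share under 0.05.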
